A study of Mus musculus with 6 samples.

How the data were processed

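The 6 libraries were grouped by the genotype label, 3 wild type and 3 Adipo-/-. Replicate numbers name the libraries in the order of deposition and pair nothing across genotypes. Per the labels' protocols, lungs were flash frozen and freeze-dried, total RNA was extracted with Trizol and a Qiagen column, and libraries followed standard Illumina protocols. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. The deposited files are Cufflinks transcript tables, 1 per library, each holding FPKM with a lower and an upper bound for the same 33295 RefSeq transcripts of 23995 genes on mm10. Per the submitters' processing notes, STAR 2.5.1j, Picard, Cufflinks, HTSeq, DESeq2 and mm10 were used, with no role or order stated. The versions of the other tools, the annotation release, read length, strand and duplicate handling are not given in the sources used here. No counts were used. Mitochondrial genes and immunoglobulin and T cell receptor segments were not among the features, so the mitochondrial list could not be tested.

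Gene FPKM was the sum over a gene's transcripts. FPKM scales each library to its own total, and the sums per library ran from 358166 to 391972. For transcripts that are the only one of their gene, the fragments behind a value were recovered from the FPKM and its upper bound, taken as 2 Poisson standard deviations. Between 80.2% and 81.8% of those under 30 fragments came out whole within 0.02, and the implied depth was 10960000, 11000000 and 10910000 fragments in the wild-type and 10400000, 13220000 and 13560000 in the Adipo-/- libraries. These depths cover counting error only. No pair of libraries shared more than 0.21% of its values, so none was a copy of another.

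Genes with a mean of at least 1 FPKM over the 6 libraries (13052) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), as Adipo-/- minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of low genes. Of the tested genes, 53 were listed at exactly 0 in some library, and 8 had a name lying on more than 1 sequence. The design assumed FPKM before the data were examined, and the test was run as planned. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.

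Before the data were examined, 48 gene lists were fixed (cell types, pathways and quality markers) with 766 entries and 714 different symbols, of which 681 were found by name, 11 by accession or synonym in the GRCm38.p6 gene table, and 22 were not found. Some lists share members and are not independent of each other. The neutrophil list shares S100a8, S100a9, Camp and Ltf with the antimicrobial list and Il1r2 with the anti-inflammatory list. Lists with at least 5 tested members, 44 of the 48, were tested with limma's camera at a preset correlation of 0.01, adjusted over these lists, and again with an estimated correlation and with fry. Counts over a list alone adjust the limma p over that list's members, and the range beside them covers the 6 fits that leave out 1 library each. The mast cell and basophil, thymus, mitochondrial and sex-linked lists had too few tested members.

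The genes named were chosen by a rule fixed before the data were examined: Adipoq; among genes past the threshold with groups apart, the 12 largest changes per direction, leaving out predicted, clone-named, antigen receptor and small RNA genes; per list, up to 4 members past the threshold, or, in a list that passed with none, the 2 with the smallest p; up to 4 members with the smallest p in 8 immune lists; and, because under 10 genes passed, the 10 smallest p per direction. Not every gene that the rule selects is named in the text. Genes outside the rule are named as chosen after their values were seen.

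Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.25, no filter and a filter of 5 FPKM, 4 other scalings, removal of mitochondrial, hemoglobin and immunoglobulin genes, the most abundant transcript per gene, eBayes without trend or robust, array weights, leaving out each library, other list tests and windows of 5 and 20 Mb. Added after seeing the data were voom on fragments estimated from FPKM and length, a threshold of 0.10, removal of a length and GC trend (loess per library; 99.1% of tested genes had a GC value from the GENCODE M21 transcripts), and leaving out genes with an exact 0. On simulated data with the 13052 genes and 6 libraries of this comparison, the same test recovered 73.8% of 2-fold and 94.2% of 4-fold changes with 9.6 false calls per run, and called a shifted list in 5 of 5 runs and 1 unshifted list over all runs. The simulation drew noise independently for each gene and changed only genes with a mean above 5 FPKM. It had no correlation between genes and no outlying library, whereas estimated list correlations in the real data reached 0.91. These rates therefore do not carry over to the real lists.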

Results

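Lung RNA was sequenced from 6 C57BL/6 mouse lung samples, 3 labelled wild type and 3 labelled Adipo-/-, a genotype read here as lacking adiponectin, the hormone that fat cells secrete and that Adipoq encodes. The mice, aged 32 postnatal days, had their neutrophils depleted with an antibody to Ly6G on the day before and the day after infection, and received 10000000 Aspergillus fumigatus of the clinical isolate Af293, a mould that infects the lung when neutrophils are missing. The comparison asks how the lung transcriptome under infection differs between the genotypes. Uninfected lungs were not analysed here. Each value describes infected tissue. Transcript levels were deposited as FPKM (fragments per kilobase of transcript, scaled to each library's total of fragments). The bounds deposited with them implied 10400000 to 13560000 fragments per library, and 12479 to 13205 genes reached 1 FPKM. The 10 most abundant genes took 5.9% to 6.6% of the FPKM, led in the wild-type libraries by the club cell secretoglobin Scgb1a1 and the surfactant gene Sftpc. Xist lay between 31.8 and 38.8 FPKM in all 6 libraries and Ddx3y, Eif2s3y, Uty and Kdm5d at or under 0.045 FPKM in each of them.

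Adipoq itself was measured first. Its level was 1.94, 2.58 and 5.78 FPKM in the wild-type libraries and 0.086, 0.605 and 0.393 FPKM in the Adipo-/- libraries, so that no Adipo-/- library reached any wild-type library (the smallest two-sided exact permutation p for 3 against 3 is 0.10). These levels rested on 23.7, 31.9 and 68.7 implied fragments against 1, 9 and 6. Adipoq lies on chromosome 16 from 23146536 to 23157968 in mm10. Its log2 change of FPKM + 1 was -1.63 ± 0.32 (SE, n = 3 per genotype), and limma gave an adjusted p of 0.0880, which failed the threshold of 0.05. Other fat cell genes differed beside it. Counts of members over a list alone are followed in brackets by their range with each library left out in turn. Of the 11 tested adipocyte markers, 6 fell (2 to 5) and 2 rose (1 to 3) adjusted over the list alone, and 0 passed over all genes. Among those that fell, named here after their values were seen, the hormone resistin (Retn) went from 4.15 ± 0.853 to 0.813 ± 0.831 FPKM (SD, n = 3), and carbonic anhydrase 3 (Car3) and adipsin (Cfd) had log2 changes of -2.10 and -1.13. Without Adipo-/- replicate 3, 4 fell and 1 rose over the list alone, the change of Car3 was -1.30 and the list's median was -0.39, against -0.60 with all libraries. As a list, adipocyte markers did not pass (camera adjusted p = 0.2235). The 14 tested genes for adiponectin receptors and signalling, Adipor1 and Adipor2 included, had a median log2 change of -0.02, with 0 members past the threshold over the list alone (0 to 1 rose) or over all genes (camera adjusted p = 0.891, with the test upward while the mean was -0.04).

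**Figure D1:**
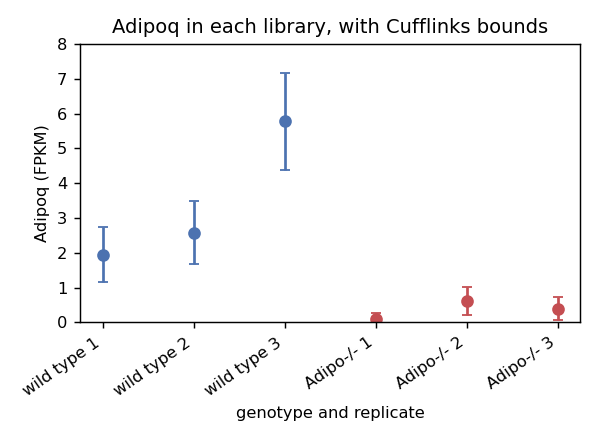
Adipoq in FPKM (vertical axis) in each of the 6 libraries (horizontal axis), with bars for the Cufflinks lower and upper bounds. The wild-type libraries lie between 1.94 and 5.78 FPKM and the Adipo-/- libraries between 0.086 and 0.605 FPKM.

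Between the genotypes 6 genes differed past the threshold. Polr2k, which encodes a small subunit shared by the RNA polymerases, fell from 34.8 ± 5.27 to 6.81 ± 1.11 FPKM (log2 change -2.19 ± 0.15, adjusted p = 0.0229). Rec8, a meiotic cohesin subunit, fell from 2.25 ± 0.11 to 0.107 ± 0.009 FPKM (-1.55 ± 0.13, adjusted p = 0.0311). Ide, the insulin-degrading enzyme, fell from 24.3 ± 1.25 to 11.7 ± 0.956 FPKM (-0.999 ± 0.095, adjusted p = 0.0318). The other 3 are predicted or clone-named genes outside the naming rule, given here after their values were seen. BC117090, a member of the stefin A family of protease inhibitors on chromosome 16, was listed at 0, 1.51 and 0 FPKM in wild-type and 29.8, 64.7 and 71.1 FPKM in Adipo-/- libraries and rose (5.28 ± 0.45, adjusted p = 0.0311). Gm8615 rose as well (1.41 ± 0.13, adjusted p = 0.0318), and 1700024G13Rik, listed at 0.779, 0 and 0 FPKM in the Adipo-/- libraries, fell (-2.78 ± 0.26, adjusted p = 0.0318). In mm10 Polr2k lies on chromosome 15 from 36174010 to 36177012, Rec8 on chromosome 14 from 55618166 to 55625395, Ide on chromosome 19 from 37268741 to 37330613, BC117090 on chromosome 16 from 36321665 to 36334332, Gm8615 on chromosome 5 from 149154128 to 149156192 and 1700024G13Rik on chromosome 14 from 32376502 to 32388373. The stefin genes are similar copies, so fragments of BC117090 and its neighbours were not separated with certainty.

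These 6 were the genes that passed among 13052 tested with limma, 2 higher and 4 lower in Adipo-/- lungs, while 3756 genes (28.8%) had an unadjusted p under 0.05. The groups did not overlap for 4804 genes (36.8%, where chance gives 10%), 1964 of them higher and 2840 lower. The calls depended on single libraries. All 6 ended without wild-type replicate 1 (adjusted p of 0.113 for Polr2k and 0.175 for the others) or Adipo-/- replicate 2 (0.166 for Polr2k, up to 0.214 for Gm8615). Without wild-type replicate 2 BC117090 alone of the 6 passed (adjusted p = 0.0179), and without wild-type replicate 3 Polr2k alone (adjusted p = 0.0424), while the log2 changes of all 6 kept their direction. The count of genes moved too: it was 1445 without Adipo-/- replicate 1, 13 without Adipo-/- replicate 3, 1 without Adipo-/- replicate 2, and 1, 3 and 2 without wild-type replicates 1, 2 and 3. Weighting libraries by their scatter gave 2572 genes and a threshold of 0.10 gave 1492, whereas 0 genes passed with limma voom on estimated fragments.

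The genes with the smallest p beyond those that passed did not pass over all genes and are given by direction. On the higher side stood the formyl peptide receptor Fpr1 (log2 change 1.18 ± 0.19), the paired immunoglobulin-like receptors Pira6 (0.79) and Pira7 (1.25), the lipopolysaccharide-degrading Aoah (0.72), the macrophage adhesion receptor Emr4 (1.14) and Igsf6 (0.82), together with Snhg3 (0.89), Matn2 (1.23), Lars (0.62) and Rpl30 (0.83), each with an adjusted p of 0.0880. With only the most abundant transcript per gene the change of Rpl30 was 0.18. Rpl30 overlaps Gm12191 on chromosome 15, and fragments of the overlap cannot be told apart; Gm12191 had a log2 change of -0.90. On the lower side, after Polr2k, Rec8 and Ide, stood the muscle gene Pdlim3 (-1.19, adjusted p = 0.0654), Spink4 (-1.55), the antioxidant esterase Pon1 (-1.60), Ppil6 (-1.04), Six5 (-0.93), the lysosomal receptor Scarb2 (-0.75) and Uckl1os (-0.86), with adjusted p of 0.0880.

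**Figure D2:**
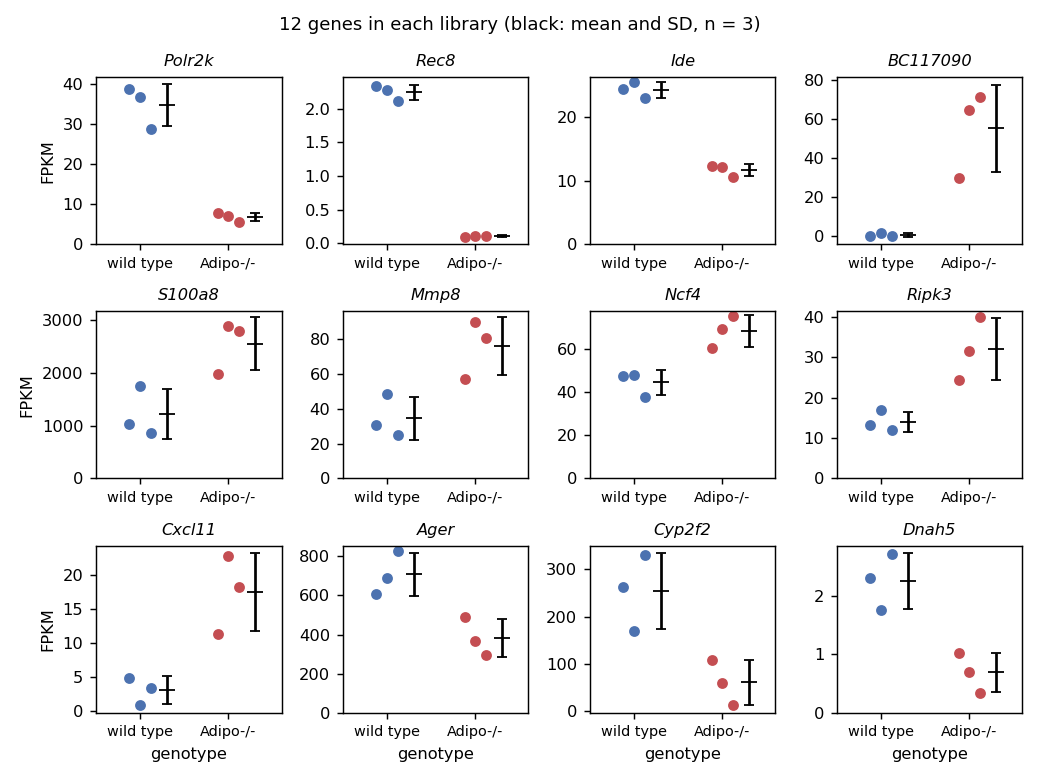
FPKM (vertical axes) of 12 genes in each library of the 2 genotypes (horizontal axes), with the mean and SD of each genotype in black (n = 3). For Ide the wild-type libraries lie between 23.0 and 25.5 FPKM and the Adipo-/- libraries between 10.6 and 12.3, and for each of these genes no Adipo-/- library overlaps a wild-type library.

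Most tested neutrophil markers were higher in Adipo-/- lungs even though every animal had been depleted of neutrophils. Of 15 tested neutrophil markers, 12 rose adjusted over the list alone (0 to 12) and 3 did not pass, while 0 passed over all genes. The log2 change was positive for 13 and negative for 2. Mpo and Elane were under the filter, and their levels overlapped between the genotypes. The median log2 change was 1.12 (camera adjusted p = 1.02e-05; adjusted p = 0.686 with an estimated correlation). The neutrophil collagenase Mmp8 rose from 34.6 ± 12.2 to 75.7 ± 16.6 FPKM, the calprotectin subunit S100a8 from 1212 ± 472 to 2544 ± 497, the stefin Stfa2l1 from 69.9 ± 44.1 to 330 ± 131 and the activating receptor Trem3 from 9.25 ± 1.27 to 17.8 ± 4.19. Adipo-/- replicate 3 stood apart from the other libraries across genes (Pearson r of 0.901 to 0.965 with them, against 0.950 to 0.985 among the rest). Without it the neutrophil median was 0.94, 3 members rose over the list alone and the list still passed (adjusted p = 0.000122). Wild-type replicate 2 had the highest neutrophil median among wild-type libraries (0.58), next to 0.61 in Adipo-/- replicate 1.

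Genes of the phagocyte oxidative burst and of cell death moved the same way. Of 16 genes for NADPH oxidase and oxidative stress, 11 rose (0 to 11) and 1 fell (0 to 1) adjusted over the list alone, with 0 over all genes (median 0.50, camera adjusted p = 2.4e-05). The oxidase subunit Ncf4 rose from 44.6 ± 5.82 to 68.3 ± 7.39 FPKM, and catalase (Cat) fell from 48.1 ± 6.18 to 31.4 ± 3.35. Of 14 inflammasome and cell death genes, 5 rose (5 in each) and 1 fell (0 to 1) over the list alone, with 0 over all genes (median 0.37, camera adjusted p = 0.000625). The necroptosis kinase Ripk3 rose from 14.0 ± 2.52 to 32.1 ± 7.76 FPKM and Naip2, which encodes a sensor of the inflammasome, from 18.3 ± 2.21 to 31.8 ± 4.37. Both lists had an adjusted p of 0.686 with an estimated correlation. Without Adipo-/- replicate 3 their medians were 0.41 and 0.34 and both lists passed, with 10 and 5 members that rose over the list alone. Without wild-type replicate 2 the median of the cell death list was 0.21.

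Chemokines and cytokines were higher as lists, with wide spread between Adipo-/- libraries. Of 26 chemokines, 3 rose (0 to 16) and 0 fell (0 to 1) over the list alone and 0 passed over all genes (median 1.02, camera adjusted p = 0.000492). Cxcl11 rose from 3.11 ± 2.04 to 17.5 ± 5.73 FPKM, the B cell attractant Cxcl13 from 50.1 ± 16.96 to 108 ± 15.9 and Ccl20, ligand of CCR6, from 9.97 ± 3.11 to 27.7 ± 11.8, while the lymphatic chemokine Ccl21a was at 42.3 ± 17.2 and 10.3 ± 8.52 and did not pass (log2 change -2.27, and -1.46 without Adipo-/- replicate 3). Per library the chemokine median was 0.39, -0.24 and -0.11 in wild-type and 0.03, 0.72 and 1.73 in Adipo-/- lungs, so the genotypes overlapped. The median change was 0.47 without Adipo-/- replicate 3, where 0 chemokines rose over the list alone. Without Adipo-/- replicate 1, 16 rose. Of 17 proinflammatory cytokine genes 0 passed over the list alone (0 to 9 rose, 9 without Adipo-/- replicate 1) or over all genes, and the list passed (median 0.62, 0.34 without Adipo-/- replicate 3, camera adjusted p = 0.00227), although wild-type replicate 1 (0.45) lay above Adipo-/- replicate 1 (0.08) in the median per library. Its leading members were the growth factor Csf2 (log2 change 1.09), Il1f9 (0.84), the alarmin Il1a (1.05) and Il23a (0.62), of which Il1a and Il23a were at 0.63 and 0.29 without Adipo-/- replicate 3. Both lists had an adjusted p of 0.686 with an estimated correlation.

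The type 17 list passed (median 0.30, camera adjusted p = 0.0372; adjusted p = 0.686 with an estimated correlation). Of its 15 members, 2 rose (0 to 6), Ccl20 and the receptor Il17ra (log2 change 0.42), and 1 fell (0 to 1) over the list alone, with 0 over all genes, and the iron-binding Lcn2 had a change of 0.68. Its call ended without wild-type replicate 2, wild-type replicate 3 or Adipo-/- replicate 3 (adjusted p = 0.106, 0.0725 and 0.106). Its median was 0.15 without the last and 0.48 without Adipo-/- replicate 1. The 12 tested type 2 response genes did not pass (median 0.45, and 0.23 without Adipo-/- replicate 3, camera adjusted p = 0.0783), with 0 members over the list alone (0 to 7 rose, 0 to 1 fell). Its smallest p were those of arginase Arg1 at 45.9 ± 36.0 and 245 ± 185 FPKM and the chitinase-like Chil3 (0.71), Il4ra (0.34) and Chil4 (0.66). The 22 interferon-gamma genes did not pass either (median -0.08, camera adjusted p = 0.885): Cxcl11 rose over the list alone (0 to 1) and 0 members fell (0 to 10, 10 without wild-type replicate 2), whereas the class II transactivator Ciita (-1.31) and the class II genes Cd74 (-0.81) and H2-Aa (-0.89) did not pass. Without wild-type replicate 2 the interferon-gamma list passed as lower. The 22 type I interferon-stimulated genes passed as a list (median 0.20, camera adjusted p = 0.0329; adjusted p = 0.794 with an estimated correlation) with 0 members past over the list alone (0 to 1 fell) or over all genes. Rtp4 (0.49) and Isg15 (0.60) led it, with changes of 0.17 and 0.18 without wild-type replicate 2. That call ended without Adipo-/- replicate 3 (median 0.10, adjusted p = 0.248), and without wild-type replicate 2 the test turned downward (median -0.14, adjusted p = 0.2115), whereas the median was 0.40 and 0.36 without wild-type replicates 1 and 3.

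Receptors for fungi and antimicrobial proteins were also higher as lists. Of 26 fungal recognition receptors and adaptors, 0 passed over the list alone (0 to 7 rose, 0 to 1 fell) or over all genes (median 0.30, camera adjusted p = 0.00777). The complement receptor subunits Itgam (log2 change 1.08) and Itgb2 (0.44), the C-type lectin Clec4d (0.75) and the kinase Syk (0.34) had the smallest p. Of 19 antimicrobial and nutritional immunity genes, 9 rose over the list alone (0 to 9, and 0 without Adipo-/- replicate 3) and 0 over all genes (median 0.57, camera adjusted p = 0.0203), among them the acute-phase protein Saa3, from 1941 ± 317 to 3212 ± 243 FPKM, and S100a8. Both lists had an adjusted p of 0.686 with an estimated correlation. Without Adipo-/- replicate 3 the fungal recognition median was 0.27 and passed, while the antimicrobial median was 0.16 and did not (adjusted p = 0.0790), nor did it pass without wild-type replicate 1 (adjusted p = 0.0878). Of 5 tested eosinophil markers, 2 rose over the list alone (0 to 3) and 0 over all genes (median 0.96, camera adjusted p = 0.0165; adjusted p = 0.686 with an estimated correlation). These were Cebpe (1.41 ± 0.44), a factor for granulocyte maturation that neutrophil precursors also use, and the ribonuclease Ear6 (1.25). The levels of both overlapped between the genotypes. Siglece (0.67) and Prg2 (0.96) followed and did not pass. The list's median in wild-type replicate 2 (0.65) lay above those in Adipo-/- replicates 1 and 2 (0.63 and 0.42). The eosinophil peroxidase Epx stayed at or under 0.444 FPKM in every library. Without wild-type replicate 1 the eosinophil call ended (adjusted p = 0.0550), and the median was 1.62 without wild-type replicate 2 and 0.46 without Adipo-/- replicate 3, where 0 members rose over the list alone. Prg2 was at 1.62, 0.57 and 0.46 without wild-type replicate 2, wild-type replicate 3 and Adipo-/- replicate 3, and Siglece at 0.35 without the last.

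Of 7 tested platelet and megakaryocyte markers, 3 rose over the list alone (0 to 5, and 0 without Adipo-/- replicate 3, where the median was 0.59 and the list passed) and 0 over all genes (median 0.75, camera adjusted p = 0.00579; adjusted p = 0.686 with an estimated correlation). Platelet factor 4 (Pf4) rose from 30.5 ± 17.96 to 114 ± 62.8 FPKM and the integrin Itga2b from 1.95 ± 0.66 to 3.95 ± 1.00. The 13 anti-inflammatory mediators passed as a list (median 0.33, camera adjusted p = 0.00586) with 0 members over the list alone (0 to 7 rose, 0 to 1 fell) or over all genes. Arg1 (2.41) and the decoy receptor Il1r2 (2.03) led it. Il1r2 is also in the neutrophil list, and its levels overlapped between the genotypes. Of 13 glucocorticoid-responsive and stress genes, 2 rose over the list alone (0 to 5) and 0 over all genes (median 0.68, camera adjusted p = 0.00323), the kinase Sgk1 (0.70, and 0.42 with only the most abundant transcript per gene) and the metallothionein Mt2 (1.85). Both had an adjusted p of 0.686 with an estimated correlation. Both calls ended without Adipo-/- replicate 3 (medians 0.25 and 0.23, adjusted p = 0.0828 and 0.0860, with 0 members of either over the list alone).

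Genes of the airway and alveolar epithelium were lower in Adipo-/- lungs. All 13 tested ciliated cell markers fell adjusted over the list alone (6 to 13), with 0 over all genes (median -1.20, camera adjusted p = 4e-06), and the 13 fell without Adipo-/- replicate 3 too (median -0.87). The axonemal genes Spag6 and Dnah5 fell from 3.88 ± 0.33 to 1.34 ± 0.48 and from 2.27 ± 0.48 to 0.691 ± 0.34 FPKM. Of 10 markers of the gas-exchanging AT1 cells, 9 fell over the list alone (0 to 10) and 0 over all genes (median -0.82, camera adjusted p = 0.000195), among them Emp2 (log2 change -0.67) and Ager, from 709 ± 111 to 383 ± 97.7 FPKM. Of 13 markers of the surfactant-making AT2 cells, 1 fell over the list alone (0 to 5) and 0 over all genes (median -0.50, camera adjusted p = 0.00227). This was Hc, which encodes complement C5 (53.3 ± 28.0 to 6.15 ± 4.71 FPKM), and Lpcat1 (-0.55) followed without passing. The 3 lists had an adjusted p of 0.686 with an estimated correlation, and each passed without Adipo-/- replicate 3, where 7 AT1 and 1 AT2 markers fell over the list alone.

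Of 13 club and goblet cell markers, 4 fell (0 to 6) and 0 rose (0 to 2) over the list alone, with 0 over all genes (median -0.78, camera adjusted p = 0.0452; adjusted p = 0.700 with an estimated correlation). The club cell monooxygenase Cyp2f2 fell from 254 ± 80.4 to 61.2 ± 47.7 FPKM and Chad fell as well (-1.62). That call ended without wild-type replicate 3 or Adipo-/- replicate 3 (adjusted p = 0.146 and 0.106). Without the latter 5 members fell and 2 rose over the list alone, and the change of Cyp2f2 was -1.59, against -2.40 with all libraries. Of 18 fibroblast and matrix genes, 6 fell (0 to 9) and 2 rose (0 to 3) over the list alone, and 0 passed over all genes (median -0.84, camera adjusted p = 0.0372; adjusted p = 0.686 with an estimated correlation). The matrix gene Mfap4 fell from 398 ± 134 to 29.3 ± 24.2 FPKM and the integrin ligand Npnt from 77.5 ± 11.9 to 43.7 ± 9.82 (log2 change -0.83, and -0.49 with only the most abundant transcript per gene). The fibroblast median was -0.38 without Adipo-/- replicate 3, with 5 members that fell and 0 that rose, and the call ended without wild-type replicate 2 or 3 (adjusted p = 0.0800 and 0.0567). Lists that did not pass were endothelial (median -0.40, and -0.10 without Adipo-/- replicate 3, with 2 of 15 members that fell over the list alone (0 to 7, and 7 without that library) and 0 that rose (0 to 1), camera adjusted p = 0.0654), smooth muscle and pericyte (-0.60, and -0.20 without that library, 3 of 11 fell (1 to 4) and 1 rose (0 to 2), adjusted p = 0.113) and mesothelial markers (-0.09, 0 of 8, with 0 to 3 that fell and 0 to 1 that rose, adjusted p = 0.978).

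Of the lymphocyte and macrophage lists, B cell markers passed as lower in Adipo-/- lungs and the others did not pass with all libraries. The 9 tested B cell and plasma cell markers passed as a list (median -0.51, camera adjusted p = 0.0452; adjusted p = 0.700 with an estimated correlation) with 0 members over the list alone (0 to 3 fell) or over all genes, among them Cd79a (log2 change -0.89). That call ended without wild-type replicate 1, wild-type replicate 3 or Adipo-/- replicate 3 (adjusted p = 0.1445, 0.0764 and 0.125), and without the last the median was -0.20 and the change of Cd79a -0.46. Lists that did not pass were T cell (median -0.46, 0 to 6 fell, camera adjusted p = 0.0850), NK cell (-0.23, adjusted p = 0.589), dendritic cell (-0.07, mean -0.05 with the test upward, 0 to 2 rose and 0 to 2 fell, adjusted p = 0.697), monocyte and inflammatory macrophage (0.23, 0 to 3 rose and 0 to 4 fell, adjusted p = 0.2075) and alveolar macrophage markers (-0.09, mean 0.03 with the test upward, adjusted p = 0.885), the last with 2 of 16 members that fell (0 to 3) and 0 that rose (0 to 2) over the list alone. Without wild-type replicate 2 the T cell and NK cell lists passed as lower and 6 of 10 T cell markers fell over the list alone. The T cell list also passed as lower with median-of-ratios scaling and with a length and GC trend removed. Cell cycle genes (-0.08, adjusted p = 0.888) and erythroid (-0.50, adjusted p = 0.697), cardiac muscle (-0.31, 0 to 6 fell, adjusted p = 0.581) and skeletal muscle markers (-0.20, adjusted p = 0.978) did not pass with all libraries. Without Adipo-/- replicate 3 the cell cycle median was 0.15 and that list passed (camera adjusted p = 0.00272). The medians without that library were -0.07 for cardiac muscle, -0.76 for skeletal muscle and -0.06 for NK cell markers. Too few members for a list test were left among the mast cell and basophil markers, where Kit and Gata2 were tested and both fell over the list alone (2 in each), and the thymus markers, where 1 of 4 fell over the list alone (0 to 1).

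The hypoxia and glycolysis list and the list of fatty acid oxidation and PPAR target genes passed as higher. The list for lipogenesis and sterol synthesis passed as lower, and the lists were not tested against each other. Of 18 hypoxia and glycolysis genes, 7 rose (0 to 13) and 1 fell (0 to 1) over the list alone, with 0 over all genes (median 0.45, 0.42 without Adipo-/- replicate 3, camera adjusted p = 0.000145). The glycolytic mutase Pgam1 rose from 33.0 ± 0.95 to 47.4 ± 6.91 FPKM, and the endothelial growth factor Vegfa fell from 157 ± 19.2 to 86.7 ± 24.99. Of 18 fatty acid oxidation and PPAR target genes, 3 rose over the list alone (0 to 6) and 0 over all genes (median 0.27, camera adjusted p = 0.0244), among them the lipid droplet coat gene Plin2, from 132 ± 38.1 to 271 ± 56.1 FPKM, and Angptl4 (1.48), a lipase inhibitor. Of this list's members, 10 had a positive and 8 a negative log2 change. Its call ended without wild-type replicate 1 (adjusted p = 0.1285), and its median was 0.17 without Adipo-/- replicate 3, with 0 members over the list alone. Both lists had an adjusted p of 0.686 with an estimated correlation. The 21 lipogenesis and sterol synthesis genes passed as lower (median -0.21, camera adjusted p = 0.0372; adjusted p = 0.700 with an estimated correlation), with 0 members over the list alone (0 to 2 fell) or over all genes and the desaturase Scd2 (-0.98) and the fatty acid synthase Fasn (-1.04) first. That call ended without wild-type replicate 1 or 3 and without Adipo-/- replicate 1 or 2 (adjusted p = 0.0649, 0.186, 0.113 and 0.0529), with a median of -0.10 without wild-type replicate 3. Small upward shifts passed for 28 cytosolic ribosomal protein genes (median 0.13, camera adjusted p = 0.00117; adjusted p = 0.700 with an estimated correlation), led by Rpl8 and Rpl32, and for 21 nuclear-encoded respiratory chain genes (median 0.10, camera adjusted p = 0.0364; adjusted p = 0.713 with an estimated correlation), led by Ndufb8 and Cycs, with 0 members of either over the list alone or over all genes. The respiratory chain call ended without wild-type replicate 1 or 3 or Adipo-/- replicate 2 (adjusted p = 0.0539, 0.0564 and 0.299), with a median of 0.02 without the last.

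In all, 24 of the 44 lists tested passed with the preset correlation, 17 higher and 7 lower, and 0 passed with an estimated correlation or with limma's fry, which asks whether a list's genes move one way on balance or in either direction. Splits of the 6 libraries that mixed the genotypes gave 8 to 27 lists with the preset correlation. Of the lists with members past the threshold over the list alone, 20 of 26 had 0 such members without at least 1 library. Of the 21 lists without such members 13 had some without at least 1 library. Without wild-type replicate 3 the neutrophil, AT1 and NADPH oxidase lists had 0 members past the threshold over the list alone, and 6 ciliated cell markers fell. After quantile normalization the split was 9 higher and 7 lower. That normalization ended the calls of 9 lists (B cell, anti-inflammatory, antimicrobial, ribosomal, fatty acid oxidation, fungal recognition, respiratory chain, type 17 and type I interferon). Removal of a length and GC trend, chosen after seeing the data, ended 8 (antimicrobial, eosinophil, fatty acid oxidation, fungal recognition, lipogenesis, respiratory chain, type 17 and type I interferon). Array weights ended 6 (B cell, anti-inflammatory, club and goblet cell, glucocorticoid, type 17 and type I interferon). Other lists passed only under an alternative. Endothelial markers passed as lower without Adipo-/- replicate 1 or 2, after quantile normalization and with a mean of at least 5 FPKM. Smooth muscle and cardiac muscle markers passed as lower without Adipo-/- replicate 2. Type 2 response genes passed as higher without Adipo-/- replicate 1. The median over a list's genes was higher in every Adipo-/- library than in every wild-type library for 7 of the 44 lists and lower for 10. Chance gives 10% for both directions together, and the smallest exact permutation p for 3 against 3 is 0.10. Among single genes the groups lay apart for 36.8%. Of the 24 called lists, the medians lay apart for 11 and overlapped between the genotypes for the others.

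**Figure D3:**
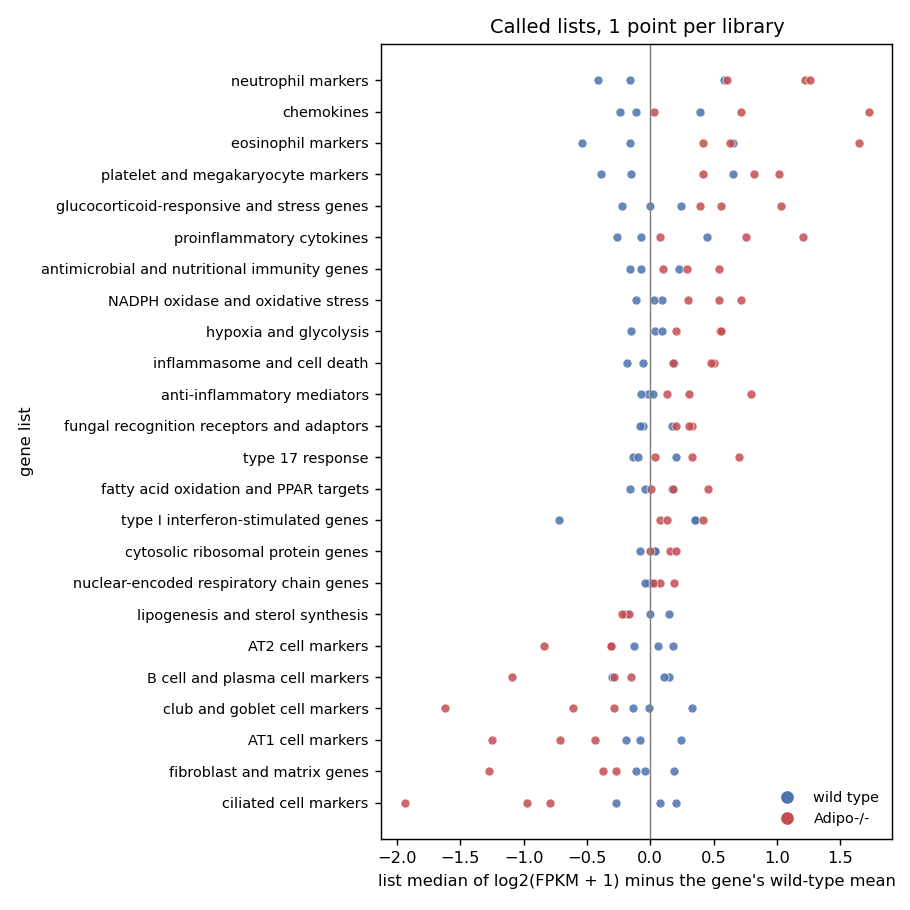
Median over the genes of each called list of log2(FPKM + 1) minus the gene's wild-type mean (horizontal axis) for the 24 called lists (vertical axis), 1 point per library and a colour per genotype. Ciliated cell markers lie at -0.79, -0.97 and -1.94 in the Adipo-/- libraries, and neutrophil markers at 0.61, 1.22 and 1.26.

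Genes near Adipoq were compared with the rest, because a targeted allele can carry a stretch of the strain it was made in. Within 10 Mb of Adipoq, 0 of 157 tested genes passed against 6 of 12894 elsewhere (two-sided Fisher exact p = 1). With 6 genes called in all, this test could hardly find an excess. An unadjusted p under 0.05 was seen for 57 of the 157, where 28.8% of all tested genes had one. Within 5 Mb it was seen for 21 of 64. Within 20 Mb, 105 of 275 had an unadjusted p under 0.05 and 1 passed (two-sided Fisher exact p = 0.12), and this gene was BC117090. In the stefin cluster that holds it, Stfa1, named after its values were seen, was at 26.4 ± 18.3 FPKM in wild-type and 1.40 ± 1.05 FPKM in Adipo-/- lungs and did not pass (adjusted p = 0.0880).

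**Figure D4:**
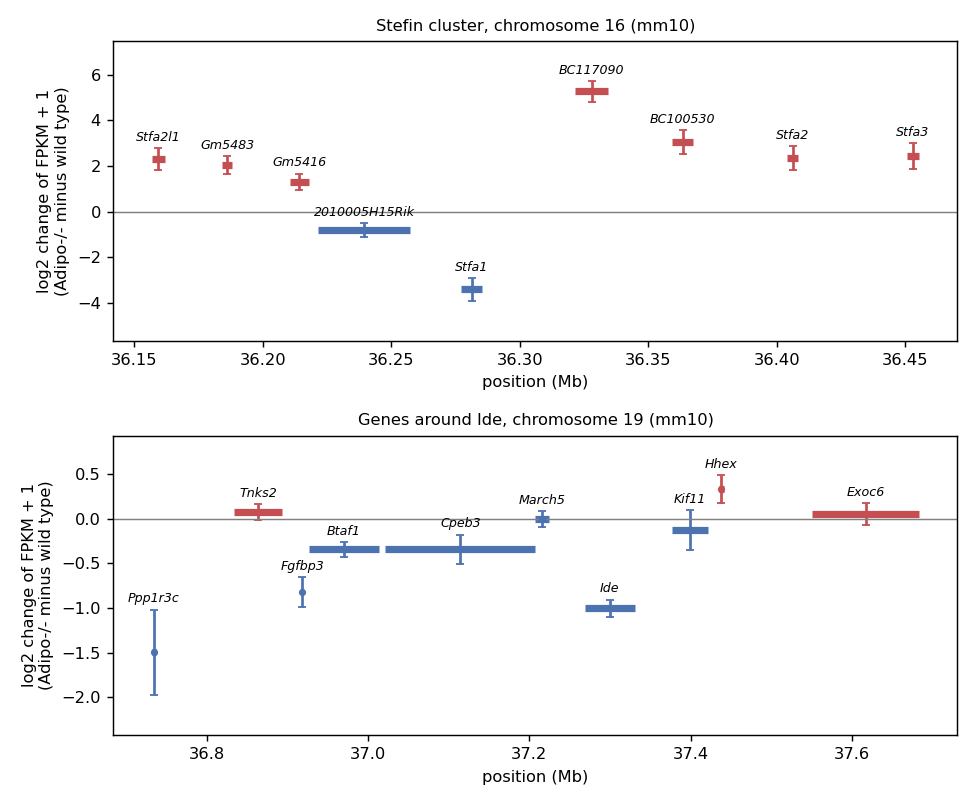
Log2 change, Adipo-/- minus wild type, with its SE (vertical axes) for the tested genes of the stefin cluster on chromosome 16 and of the region around Ide on chromosome 19, drawn at their mm10 positions (horizontal axes) with a bar for each gene's span. BC117090 lies at 5.28 and Stfa1 at -3.41, and Fgfbp3 near Ide lies at -0.82.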

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

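Of the alternatives below, voom, the threshold of 0.10, the removal of a length and GC trend and the omission of genes with an exact 0 were chosen after seeing the data. No paired analysis was possible because replicate numbers only follow the order of deposition.

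Against 6 genes past the threshold, pseudocounts of 0.1 and 0.25 gave 1 each, no filter 3, a mean of at least 5 FPKM 3, the most abundant transcript 10, array weights 2572 (1017 higher, 1555 lower), voom on estimated fragments 0 and a threshold of 0.10 gave 1492. Leaving out 1 library gave 1 to 1445 genes. The 6 genes were all among those called with array weights, without Adipo-/- replicate 1 and without Adipo-/- replicate 3. The other scalings, eBayes without trend or robust, the length and GC correction and the omission of exact 0 gave 4 to 8. The causes were not tested. The implied depth of 10400000 to 13560000 fragments limits low genes such as Adipoq.

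Of 24 lists, 0 passed with an estimated correlation, 0 with fry for 1 direction and 0 with fry for either. With the preset correlation 10 passed under all of their alternatives and 14 lost the call under at least 1. Type I interferon-stimulated genes ranged from a median of -0.14, reversed, to 0.4 when 1 library was left out. For single genes 0 reversed.

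Adipoq passed with array weights (-1.50, adjusted p = 0.0261, range over its alternatives 0.0261 to 0.329) and at a threshold of 0.10 (-1.63). Within 20 Mb of Adipoq 1 gene passed, against 0 within 10 Mb, in a window that holds more genes.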

Other observations

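The tests below were chosen after the result was seen, except the counts over other splits of the libraries and the test of Fgfbp3.

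Complement and clotting genes moved in both directions. Of 19 tested, 5 rose and 3 fell adjusted over the list alone (0 to 7 for each when 1 library was left out), with 0 over all genes (median -0.08, mean 0.06 with the test upward, camera adjusted p = 0.7265). Coagulation factors F10 (log2 change 0.89) and F7 (0.46), properdin (Cfp, 0.77), the C5a receptor C5ar1 (0.84) and the urokinase receptor Plaur (0.86, and 0.55 without Adipo-/- replicate 3) rose over the list alone. Among those that fell were C4b (-1.11) and thrombomodulin (Thbd, -1.01, and -0.61 without that library). The members named in this paragraph and the next were chosen after their values were seen.

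The clock and heat shock lists did not pass with all libraries. Of 16 circadian clock genes, Dbp (log2 change -1.17), Per3 (-0.87, and -0.34 with only the most abundant transcript per gene) and Cry2 (-0.41) fell over the list alone, with 0 over all genes (median -0.38, camera adjusted p = 0.0528, and 0.0153 without Adipo-/- replicate 3, where 5 fell; 0 to 5 with 1 library left out). Of 19 immediate early and heat shock genes, the chaperone genes Hspa1b (-0.96), Hsph1 (-0.96) and Hsp90aa1 (-0.49) fell over the list alone, with 0 over all genes (median -0.17, camera adjusted p = 0.343, and 0.0388 without Adipo-/- replicate 3, where 1 fell; 1 to 4 with 1 library left out). The clock list also passed as lower without wild-type replicate 1 or 3, with a mean of at least 5 FPKM, median-of-ratios scaling, array weights and voom, and the heat shock list with array weights. The 16 unfolded protein response genes had 0 members past over the list alone (median -0.07, camera adjusted p = 0.843). The 22 cell cycle genes had a median of -0.08, and of 0.15 without Adipo-/- replicate 3 (camera adjusted p = 0.00272).

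By list median, neutrophil markers were higher while ciliated, AT1 and AT2 markers were lower in Adipo-/- lungs. Without Adipo-/- replicate 3 the highest camera adjusted p of these 4 lists was 0.00555 with the preset correlation. With a length and GC trend removed it was 0.000704. With an estimated correlation and all libraries each list had a camera adjusted p of 0.686, so these p-values cannot decide on either feature. Without Adipo-/- replicate 3 the medians were 0.94 for neutrophil, -0.87 for ciliated, -0.59 for AT1 and -0.41 for AT2 markers. Their direction thus did not rest on that library alone. Uniform dilution of lung cells would lower structural lists alike. From the ciliated median that of the mesothelial, endothelial, fibroblast or smooth muscle list was subtracted. The difference was lower in every Adipo-/- than in every wild-type library (gaps of 0.3, 0.38, 0.29 and 0.25), so ciliated markers fell more than these lists. The ciliated list, however, was picked after its median was seen to be the lowest of the called lists, which makes such gaps likely. The smallest exact permutation p for 3 against 3 is 0.10. The gaps therefore cannot exclude dilution. Dilution stays open for AT1 and AT2 markers as well. For AT1 markers the genotypes lay apart against mesothelial markers (gap of 0.23) but overlapped against the other 3 lists (gaps down to -0.1). For AT2 markers they overlapped against all 4 (gaps down to -0.45). The degree of neutrophil depletion, the fungal burden and the genotype itself were not measured apart and stay open.

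The 10 splits of 6 libraries are too few for a share under 0.05. For genes, 1 split, the real one, gave as many as 6, and the highest other gave 1. For lists with the preset correlation, 3 splits, the real one among them, gave at least the real 24. The splits that mixed the genotypes gave 8, 11, 18, 19, 19, 20, 23, 26 and 27. The number of lists thus did not set the real split apart.

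In the stefin cluster on chromosome 16, BC117090 was higher and Stfa1 lower in Adipo-/- lungs. The 2 genes together took 6.25%, 7.09% and 5.78% of the cluster's FPKM in wild-type libraries. They took 2.86%, 3.21% and 2.94% in Adipo-/- libraries (gap of 2.57 points), where more neutrophils alone would leave that share alike. The 2 genes, however, were picked after their values were seen, which makes such a gap likely. The smallest exact permutation p for 3 against 3 is 0.10. The gap therefore cannot exclude neutrophil content as the whole cause. Fragments moved between BC117090 and Stfa1 stay open: their summed FPKM was 19.2, 48.7 and 12.9 in wild-type and 30.2, 66.1 and 73.5 in Adipo-/- libraries, which overlap (lowest wild-type minus highest Adipo-/- sum -60.6), although an exchange alone would not lower the share. A candidate explanation is a segment of another strain linked to Adipoq, which lies 13.2 Mb away: 30 of 72 tested genes between them (41.7%) had an unadjusted p under 0.05 against 28.6% elsewhere (two-sided Fisher exact p = 0.0184). Neighbouring genes are not independent, and the segment's end was set by BC117090 itself. Within 5 Mb of Adipoq 21 of 64 tested genes had an unadjusted p under 0.05, against 57 of 157 within 10 Mb and 105 of 275 within 20 Mb. The share was thus not highest nearest Adipoq, where a linked segment would lie.

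Ide was lower in Adipo-/- lungs with little spread. Scaling is argued against, since the highest log2 change of Ide over 5 rescalings was -0.93. A copy number difference of the segment holding Ide and Fgfbp3, known to vary among C57BL/6J colonies, was considered. Fgfbp3 had a ratio of means of 0.333 and Ide of 0.48. The condition fixed beforehand, Fgfbp3 lower in every Adipo-/- library with a ratio under 0.8, was thus met. The Fgfbp3 levels rested on 32.7, 28 and 41.3 implied fragments in wild-type and 13, 16 and 9 in Adipo-/- libraries. Of all tested genes, 2262 (17.3%) were likewise lower in every Adipo-/- library with a ratio under 0.8. The ratios of Btaf1, Cpeb3 and March5, which lie between Fgfbp3 and Ide, were 0.769, 0.668 and 0.997. In mm10 an unbroken segment holding both Ide and Fgfbp3 would hold March5 too, whose level was alike. March5 was not part of that condition, and the RNA level of a single gene does not measure its copy number. These levels therefore cannot decide for or against such a segment. No DNA was measured, so a copy number difference at Ide stays a hypothesis.

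Around Polr2k, 6 of 25 tested genes on chromosome 15 from 31291479 to 36291478 had an unadjusted p under 0.001, and a share of 0.0453 of 10000 shuffles of gene positions had a window with as many. With overlapping genes left out the number was 4 of 23, and the share was 0.511.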
